A study of Citrus unshiu with 8 samples.

How the data were processed

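RNA was sequenced from callus of the Satsuma mandarin cultivar ‘Guoqing No.1’ transformed with a CsFUS3 overexpression vector or an empty vector. Per the labels, the callus was kept on MT medium and induced with glycerol, and sampled after 6 weeks (colour beginning to change) or 12 weeks (embryos emerging). RNA was extracted with Trizol, treated with DNase and enriched with oligo(dT) beads, and libraries were read on the Ion Proton platform. There were 8 libraries, 2 per line and time, which the series design calls biological replicates. Whether replicates came from one transformation event is not stated, and p-values measure the spread between these samples. The 4 groups were taken from the titles and characteristics, and all per-sample columns were mapped.

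Per the file headers, the authors gave for each gene a read count, an RPKM value and the fraction of the gene length covered by reads. The deposited counts were whole numbers that summed to the total in the header of each file, and the deposited RPKM equalled the count scaled by that total and by gene length (largest relative deviation 8.88e-15). The coverage fraction was not used. Each file held one library and listed only genes with at least 1 read, so an absent gene was taken as 0. Gene models of sweet orange (29655 models, annotation source CsiDB2011_11) and gene descriptions came with the deposited files. The aligner, the counting rule, strand handling and the genome build were not given in the sources used here. Reads shared by paralogs or by overlapping genes could therefore not be assigned with certainty. Reads came from Satsuma mandarin and the models from sweet orange. None of the gene identifiers matched the reference gene table, so names rest on the best protein hit of each model.

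Totals ran from 10962672 to 11897705 counted reads per library. In the empty vector line they were 11406252 and 10962672 at 6 weeks and 11485245 and 11758718 at 12 weeks, and in the overexpression line 11897705 and 11324509, then 11174650 and 11827745. A read was found for 22920 genes in all, and for 19440 to 20487 genes per library. The 10 most abundant genes took 2.07% to 2.89% of reads. Between replicates the Pearson correlation of log CPM across genes was 0.987 to 0.991, and genes are not independent replicates. TMM factors were 0.991 to 1.01.

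Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (17394 kept), scaled by TMM and fitted with one mean per group over all 8 libraries (residual degrees of freedom 4). The robust quasi-likelihood F test was applied, and Benjamini-Hochberg adjusted p under 0.05 was called. The biological coefficient of variation was 8.13%. Changes are log2 fold changes from this fit, and CPM are group means scaled by TMM. Each standard error was derived as the absolute log2 change divided by the square root of the F statistic. The 5 comparisons were overexpression against empty vector at 6 and at 12 weeks, 12 against 6 weeks in each line, and the difference of the overexpression effect between the times. For a gene with no reads in the lower group, the fold is a bound against a floor of 3 counts over that group; for 1 to 3 reads it is a count ratio with an exact 95% interval. Shared calls of the 6 and 12 week comparisons were tested with Fisher's exact test, two-sided, among all tested genes.

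Gene lists were fixed as word patterns on the descriptions before the data were examined, 35 in all, covering embryo regulators, seed products, hormones, plastids, metabolism, defence and markers of other cell kinds. Of 22920 genes 17527 (76.5%) had an informative description. Lists of at least 5 tested genes, 33 of them, were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2. The correlation between genes was preset at 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation and fry were run beside it. Camera called 2, 8, 6, 10 and 11 lists in the 5 comparisons in the order given, and 6, 11, 6, 12 and 12 at an unadjusted p under 0.05. With an estimated correlation it called 0 in each, with 1, 3, 2, 2 and 7 at an unadjusted p under 0.05. Some members matched a list by a word only. A second set of lists without them, and with a pattern for BABY BOOM added to the embryo regulators, was chosen after member names, but before test values, were seen. The same test was run over 517 annotated groups of 10 to 300 tested genes, from 14218 genes with an annotation.

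Genes were named by a rule fixed before the data were examined. It took the FUS3-described genes, then in each comparison the 5 rising and 5 falling genes with the largest fitted change. These needed adjusted p under 0.05, at least 10 CPM in the higher group, replicates that did not overlap between groups and an informative description. It further took up to 2 rising and 2 falling members of each list with the smallest adjusted p, and up to 6 members of the hormone and embryo regulator lists. The text names a part of these. Vicilin gene Cs8g17030 was singled out after its values were seen.

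Chromosome segments were found by repeatedly splitting the order of 11888 placed genes with a mean of at least 5 CPM, into parts of at least 30 genes. Log2 changes were limited to 1.5, and a split was kept when its statistic passed the 99th percentile of 1000 shuffled gene orders (4.22 to 4.41 by comparison). Segments with a median beyond 0.1 in either direction, a limit chosen after seeing the data, were called shifted. Taken over all comparisons searched, they held 5650 genes, of which 4429 were tested. Leaving these genes out also shortens the gene lists, so a list call lost in this way need not show that the segments made it.

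The edgeR step was tested on simulated data drawn at the depth and spread of these libraries, with 50 genes changed at each fold. The changed genes all had a mean of at least 5 CPM, so recovery of weaker genes was not tested. At 1.25-fold it recovered 8% at 6 weeks, 18% at 12 weeks, 10% and 14% over time in the empty vector and overexpression lines, and 0% for the difference of effects. At 1.5-fold it recovered 70%, 66%, 68%, 70% and 34%, at 2-fold 96%, 94%, 94%, 94% and 82%, and at 4-fold 100%, 98%, 100%, 100% and 100%. False calls made up 7.43% to 9.33% of calls. In this simulation, changes of 1.25-fold and 1.5-fold differences of effects were thus mostly missed. Calls in the data were far more numerous, which makes the adjusted threshold less strict, so these shares need not carry over. Over time in the empty vector line, 137 of 256 genes annotated with structural molecule activity rose and 15 fell, at a median log2 change of 0.33.

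The alternatives were RLE scaling, library size alone, no low count filter, a filter at 5 CPM, DESeq2 1.42.0, limma on log2 RPKM with a pseudocount of 1 or 0.1 or with no filter, only the libraries of a comparison, a replicate block, each library left out in turn and a 2-fold minimum. Lists without word matches were added after member names alone were seen, and lists matched on any protein hit and the omission of shifted segments were added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Base composition of the genes was not analysed here, since no genome sequence was used.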

Results

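Callus carrying a CsFUS3 overexpression vector was compared with callus carrying the empty vector, to ask which transcripts differed as glycerol induced somatic embryos. Both lines were sampled at 6 weeks, when the colour began to change, and at 12 weeks, when embryos began to emerge. Each of the 4 groups had 2 biological replicates. FUS3 (Cs2g14320), a B3 transcription factor of seed maturation, lay on chromosome 2 at 11162789 to 11166015 on the plus strand, with 6 exons. Its reads in the empty vector libraries numbered 369 and 414 at 6 weeks and 530 and 568 at 12 weeks. In the overexpression libraries they numbered 786 and 873, then 949 and 1023. FUS3 was higher in the overexpression line at 6 weeks by a log2 fold change of 1.05 (SE 0.11, adjusted p = 3.3e-07), from 34.6 ± 3.7 to 71.6 ± 7.0 CPM (mean ± SD). At 12 weeks the log2 difference was 0.87 (SE 0.11, adjusted p = 2.9e-07), from 47.3 ± 1.1 to 86.5 ± 1.2 CPM. The 2 differences were not called different from each other (log2 difference −0.18, adjusted p = 0.40). A second gene described as FUS3 (Cs7g02780) had 1 read in all 8 libraries together. Whether reads of the introduced copy were counted with those of the resident gene was not given in the sources used here.

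At 6 weeks, when colour was beginning to change, the other embryo regulators differed in both directions. ABI3 (Cs5g34660), a B3 regulator of abscisic acid responses in seeds, rose by a log2 fold change of 0.74 (SE 0.09, adjusted p = 4.7e-06), from 422 to 702 CPM; it lies on chromosome 5, where the median change was 0.12. The receptor kinase gene SERK1 (Cs7g02890), a marker of embryogenic cells, fell by 1.22 (SE 0.16, adjusted p = 1.1e-05), from 14.4 to 6.17 CPM. LEC2 (Cs2g05780), another B3 regulator, was not called (log2 difference −0.23, adjusted p = 0.19). Of the 9 tested members of the embryo regulator list, 4 rose and 1 fell, also when adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.622). In the list with word matches removed and a BABY BOOM pattern added, 2 of 8 rose and 1 fell, also over the list alone (adjusted p = 0.876).

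All 5 tested oleosins, the coat proteins of oil bodies, rose at 6 weeks, and all 5 rose when adjusted over the list alone. The high molecular weight oleosin Cs2g27550 rose by a log2 fold change of 1.55 (SE 0.10) and oleosin 1 (Cs4g18960) by 1.53 (SE 0.11). The list median was 1.53 (adjusted p = 2.8e-05, or adjusted p = 0.493 with an estimated correlation). The group 3 late embryogenesis abundant (LEA) gene Cs1g13160 rose by 1.51 (SE 0.10), and 10 of the 40 members of the LEA list rose while 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.242). Removing members that matched only by a word, such as phloem proteins, left 23 LEA genes, of which 8 rose and none fell (adjusted p = 0.0238, or adjusted p = 0.703 with an estimated correlation). Legumin A (Cs1g23800), a seed storage protein, rose by 2.26 (SE 0.27, adjusted p = 6.7e-04), from 7.54 to 36.3 CPM. Of the 25 members of the seed storage list, 5 rose and none fell (6 adjusted over the list alone; adjusted p = 0.284).

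At 6 weeks camera called none of the tested lists of abscisic acid and gibberellin genes, the hormones named in the series title. With fry, which does not compare a list with other genes, abscisic acid signalling and gibberellin signalling were both called up (adjusted p = 0.0347). Of 29 abscisic acid signalling genes, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.0559). The receptor gene PYL9 (orange1.1t00478) rose by a log2 fold change of 1.09 (SE 0.11, adjusted p = 1.8e-07) and protein phosphatase 2C 3 (Cs8g19140), of the family that PYL receptors inhibit, by 0.87 (SE 0.12, adjusted p = 2.4e-05). Among 7 abscisic acid synthesis genes, a zeaxanthin epoxidase (Cs1g04900) fell by 0.95 (SE 0.12) and the other 6 were not called. None of 3 abscisic acid 8'-hydroxylase genes and none of 5 gibberellin 2-oxidase genes, which inactivate the hormones, was called. Among 7 gibberellin synthesis genes 2 fell and none rose; ent-kaurenoic acid hydroxylase-like Cs7g22840 was one, at 1.47 and 0.478 CPM. Of 7 gibberellin signalling genes 2 rose and none fell (2 and 1 adjusted over the list alone; adjusted p = 0.622). One of the risers was GAI (Cs6g17530), a DELLA repressor of gibberellin responses, at 0.68 (SE 0.18, adjusted p = 8.8e-03). The GAI call was lost without replicate 1 of the empty vector (adjusted p = 0.091) or replicate 2 of the overexpression line (adjusted p = 0.083), and that of Cs7g22840 without replicate 2 of the empty vector (adjusted p = 0.34) or replicate 1 of the overexpression line (adjusted p = 0.33).

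Cytosolic ribosomal protein genes were lower in the overexpression line at 6 weeks. Of 143 tested, 51 fell and none rose (68 and 2 adjusted over the list alone), with a median log2 change of −0.25 (adjusted p = 1.9e-09, or adjusted p = 0.763 with an estimated correlation). With fry the adjusted p was 0.0733. L29-1 (Cs9g02480) fell by 0.83 (SE 0.10) and L3-2 (Cs3g21570) by 1.36 (SE 0.19). Chalcone synthase 2 (Cs2g14720), at the first step of flavonoid synthesis, fell by 1.13 (SE 0.11), while its list was split, with 12 of 102 members up and 12 down (12 and 13 adjusted over the list alone). Expansin-A5 (Cs6g21460), which loosens cell walls, rose by 1.78 (SE 0.13). The largest rises by the naming rule included an omega-6 fatty acid desaturase (orange1.1t02024, log2 3.42, SE 0.32) and a gene described as the cap-binding protein CBP20 (Cs8g13710, log2 3.30, SE 0.19). An inter-alpha-trypsin inhibitor-like gene (Cs3g16740) fell by 4.31 (SE 0.23), from 31.0 to 1.56 CPM. The fall of ABC transporter ABCB11 (Cs6g20270) was 2.68 (SE 0.18).

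Over all genes, 3274 of 17394 tested differed between the lines at 6 weeks, 1803 higher and 1471 lower, or 471 and 248 at a 2-fold minimum and 1115 and 1101 without the genes of shifted chromosome segments. The count rested on every 6-week library. It was 1611 without replicate 1 and 1571 without replicate 2 of the empty vector, and 1473 and 1608 without replicates 1 and 2 of the overexpression line. Camera called no other fixed list. Nitrogen and sugar transport genes rose in 7 of 30 with none falling (8 and 1 adjusted over the list alone; median 0.08, adjusted p = 0.299). Up and down counts were 17 and 14 of 120 for auxin, 6 and 7 of 76 for the cell cycle, 16 and 20 of 132 for the cell wall, and 3 and 4 of 47 for light harvesting. Adjusted over the list alone these 4 were 20 and 15, 6 and 7, 17 and 22, and 3 and 4. Of the markers of other cells, 7 of 42 for epidermis rose and 1 fell, 4 and 2 of 21 for vascular cells, and 1 and 3 of 15 for the shoot meristem. For the vascular, pathogenesis-related and peroxidase lists the median was below 0 (−0.07, −0.04 and −0.03) while the mean (0.01, 0.07 and 0.11) and the direction of the test were up. For auxin the median (0.04) and the test were up and the mean was −0.11.

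**Figure D1:**
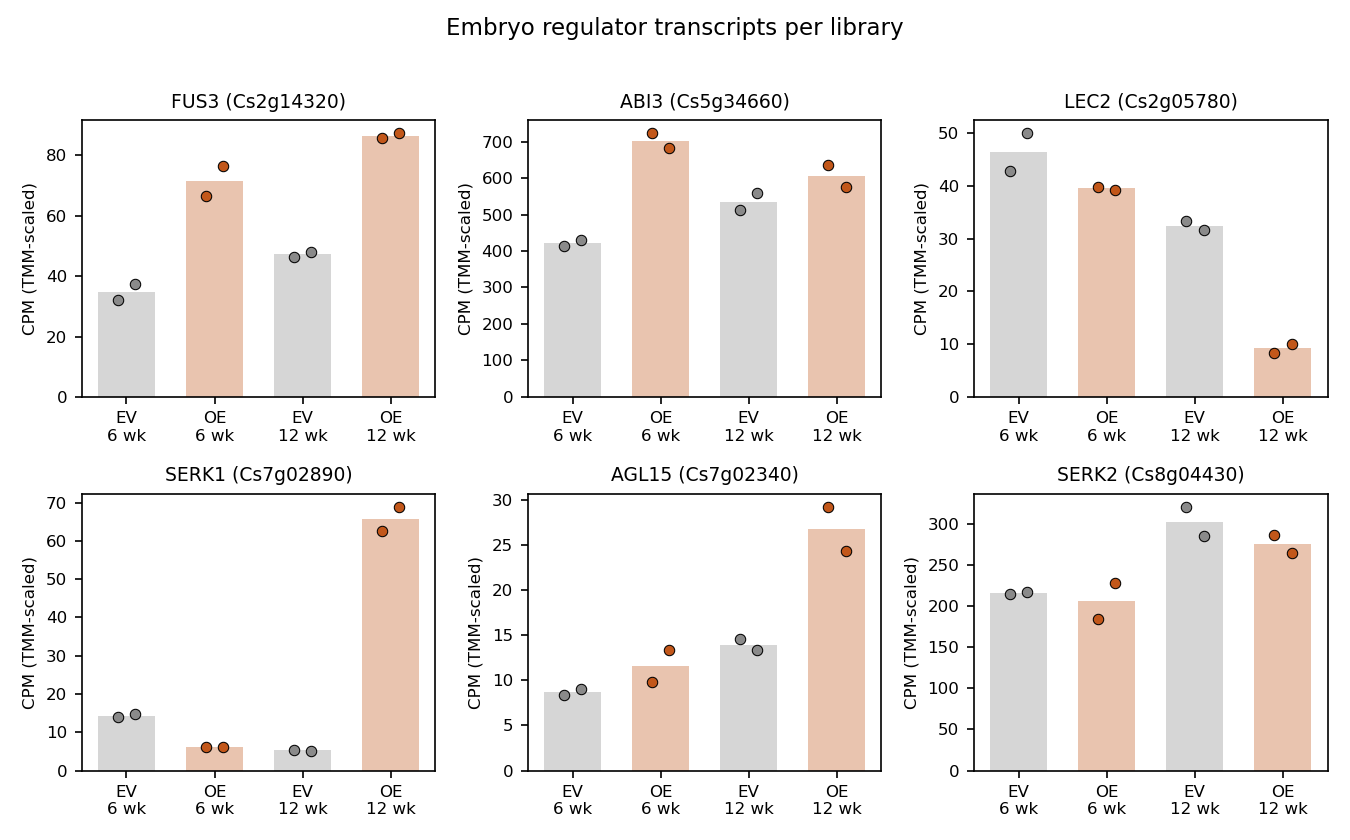
Transcript levels (y axis, CPM) of 6 embryo regulator genes in empty vector and overexpression callus at 6 and 12 weeks; bars give group means and points the 2 libraries of each group. FUS3 was higher in the overexpression line at both times, whereas SERK1 went from 6.17 to 65.8 CPM between the times in that line.

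At 12 weeks, when embryos began to emerge, the lines differed in several regulators of embryo and organ growth. SERK1 rose by a log2 fold change of 3.64 (SE 0.15, adjusted p = 2.1e-15), from 5.26 CPM in the empty vector line to 65.8. AINTEGUMENTA (Cs1g21310), an AP2 factor of organ growth, rose by 6.65 (SE 0.25), from 0.599 to 61.8 CPM, although it lies on a chromosome 1 segment with a median of −0.47. AGL15 (Cs7g02340), a MADS-box factor of embryos, rose by 0.94 (SE 0.17, adjusted p = 4.1e-05). LEC2 fell by 1.82 (SE 0.14, adjusted p = 1.9e-10), from 32.5 to 9.19 CPM, on a chromosome 2 segment with a median of −0.79. ABI3 was no longer called (log2 difference 0.18, adjusted p = 0.11). The embryo regulator list had 4 of 9 members up and 2 down, also over the list alone, and was not called (adjusted p = 0.278). In the changed list 3 of 8 rose and 1 fell, also over the list alone (adjusted p = 0.434). Of 15 genes in the shoot meristem list 9 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0706). The list took any description with the word WUSCHEL. Its member WOX11 (Cs5g27430), up by 3.68 (SE 0.19), therefore need not mark the shoot meristem. Epidermis markers rose in 14 and fell in 13 of 42, and vascular markers rose in 9 and fell in 4 of 21, with neither list called.

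Legumin A, a vicilin gene and the LEA and seed storage lists were higher in the overexpression line at 12 weeks. Legumin A, in the lowered segment of chromosome 1, went from 54.5 to 257 CPM (log2 2.24, SE 0.20) and the vicilin gene Cs8g17030 from 185 to 754 CPM (log2 2.03, SE 0.31, adjusted p = 4.3e-03). The LEA gene Cs9g04210 (Lea5) rose by 2.58 (SE 0.13), from 252 to 1511 CPM. Of 40 members of the LEA list 21 rose and 9 fell, and the same numbers held adjusted over the list alone (median 0.47, adjusted p = 0.0394, or adjusted p = 0.54 with an estimated correlation). That call was lost without replicate 2 of the empty vector at 12 weeks (adjusted p = 0.171) and without any one of the 6-week libraries (adjusted p = 0.0897 to 0.108), with no low count filter (adjusted p = 0.097), or without the genes of shifted chromosome segments (adjusted p = 0.357). Of the 23 LEA genes left without word matches, 16 rose and 3 fell (median 2.55, adjusted p = 2.3e-04, or adjusted p = 0.4 with an estimated correlation). The seed storage list had 16 of 25 members up and 3 down (16 and 4 adjusted over the list alone), with a median of 1.85 (adjusted p = 2.6e-04, or adjusted p = 0.302 with an estimated correlation). Most of its members were not storage proteins by description. They were basic 7S globulins, which are proteinase-like proteins, such as Cs9g06160 (log2 5.56, SE 0.17), and lipid transfer or protease inhibitor proteins, such as Cs5g09390, which fell by 0.98 (SE 0.09). With such members removed 3 genes were tested and 2 rose, too few to test as a list. Of the 5 oleosins 4 rose and none fell (4 and 1 adjusted over the list alone; adjusted p = 0.118), Cs2g27550 from 377 to 1069.6 CPM.

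The light harvesting, chlorophyll and carotenoid lists were also higher in the overexpression line at 12 weeks. Of 47 light harvesting and photosystem genes 27 rose and 2 fell (28 and 2 adjusted over the list alone), with a median of 1.23 (adjusted p = 1.4e-04, or adjusted p = 0.406 with an estimated correlation). The chlorophyll a/b-binding gene Cs2g19680 rose by a log2 fold change of 3.26 (SE 0.16), from 8.76 to 84.4 CPM. Of 17 chlorophyll synthesis genes 10 rose and 2 fell, also over the list alone (adjusted p = 0.0112, or adjusted p = 0.342 with an estimated correlation), a call lost with lists matched on any protein hit (adjusted p = 0.111). The Mg-protoporphyrin ester cyclase Cs6g16200 rose by 2.57 (SE 0.13). Among 16 carotenoid genes 10 rose and none fell, also over the list alone (median 0.65, adjusted p = 4.6e-03, or adjusted p = 0.302 with an estimated correlation), with beta-carotene hydroxylase 2 (Cs9g19270) up by 2.43 (SE 0.33). Carbon fixation genes were split, 6 of 25 up and 4 down, or 6 and 3 adjusted over the list alone (median −0.14, mean 0.04, adjusted p = 0.906); a RuBisCO small chain (Cs4g03580) rose by 2.82 (SE 0.21).

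Flavonoid and phenylpropanoid genes had the lowest list p at 12 weeks. Of 102 tested, 57 rose and 14 fell (59 and 14 adjusted over the list alone; median 0.84, adjusted p = 2.1e-05, or adjusted p = 0.101 with an estimated correlation). Chalcone synthase 2 rose by a log2 fold change of 3.35 (SE 0.12), from 82.0 to 838 CPM. Ethylene response factors rose in 30 of 53 members and fell in 7, also over the list alone (adjusted p = 5.9e-04, or adjusted p = 0.302 with an estimated correlation). ACC oxidase 1 (Cs4g13870), the last enzyme of ethylene synthesis, rose by 3.90 (SE 0.12), from 18.2 to 271 CPM. The ethylene synthesis list was split and not called, with 8 of 23 members up and 6 down (9 and 6 adjusted over the list alone; median 0.14, adjusted p = 0.735). At a 2-fold minimum 4 of its members rose and 5 fell. With word matches removed 3 of 6 rose and 2 fell (adjusted p = 0.434). Of 85 pathogenesis-related genes 40 rose and 13 fell, also over the list alone (adjusted p = 0.0248, or adjusted p = 0.302 with an estimated correlation), a call lost without the genes of shifted chromosome segments (adjusted p = 0.061) or with a filter at 5 CPM (adjusted p = 0.0691). The PR-10 gene Cs9g03630 rose from 150.5 to 1204 CPM, whereas the thaumatin-like gene orange1.1t03023 fell by 2.60 (SE 0.16).

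Camera called none of the abscisic acid and gibberellin lists it tested at 12 weeks, and single members changed. With fry, which does not compare a list with other genes, these 5 lists were called up (adjusted p = 0.00181 to 0.00808). Fry values as low were not particular to these lists. It also called carbon fixation, auxin and fatty acid synthesis genes up (adjusted p = 0.011, 8.2e-05 and 0.00262), which camera did not call. Ribosomal protein and glycerol use genes were not called by fry (adjusted p = 0.81 and 0.525). Abscisic acid catabolism, with 2 of 3 genes up, was too short to test. The abscisic acid 8'-hydroxylase 1 gene (Cs6g19380), for the main step of abscisic acid breakdown, rose by a log2 fold change of 2.98 (SE 0.25, adjusted p = 5.2e-10), from 2.33 to 18.4 CPM. In abscisic acid synthesis 4 of 7 genes rose and 2 fell, also over the list alone (adjusted p = 0.348), with zeaxanthin epoxidase Cs2g26760 up by 0.75 (SE 0.14) and Cs1g04900 down by 0.50 (SE 0.11). In signalling 11 of 29 rose and 7 fell, also over the list alone (adjusted p = 0.348); the abscisic acid-induced HVA22 gene orange1.1t02608 rose by 1.49 (SE 0.16), HVA22-like i (Cs6g13900) fell by 3.06 (SE 0.20) and ABI4 (Cs7g30830) fell by 0.61 (SE 0.11). In gibberellin synthesis 4 of 7 rose and 2 fell, with the same counts over the list alone (adjusted p = 0.387). Ent-kaurene oxidase (orange1.1t01910) rose by 2.72 (SE 0.22), while gibberellin 20-oxidase 1 (Cs5g28750), a late enzyme of the pathway, fell by 3.56 (SE 0.56), from 4.25 to 0.349 CPM. Of 5 gibberellin 2-oxidases 1 rose and 1 fell (adjusted p = 0.532), Cs9g01770 by 3.29 (SE 0.35). The DELLA genes GAI1 (Cs2g16940) and GAI rose by 1.40 (SE 0.15) and 1.42 (SE 0.17), and gibberellin signalling as a list had 3 of 7 up and 3 down (median −0.20, mean 0.10, adjusted p = 0.954).

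Of all 17394 genes, 9476 differed between the lines at 12 weeks, 4753 higher and 4723 lower. With only the 4 libraries of each comparison the counts were 5242 at 6 weeks and 8501 at 12 weeks. At a 2-fold minimum 2382 were higher and 1223 lower at 12 weeks, and without the genes of shifted chromosome segments 3650 and 3127. The largest rises by the naming rule started from no reads in the empty vector line. A pectinesterase gene (Cs2g07660) reached 34.7 CPM, at least 266-fold over a floor of 3 counts, and a gene described as mitochondrial chaperone BCS1-B (Cs4g03390) at least 133-fold. The largest falls included a calcium ATPase (Cs3g10680, log2 −5.24, SE 0.39) and a fragment of an RNA-dependent RNA polymerase (Cs5g14110, log2 −6.72, SE 0.31). These floors cover counting error only. Ribosomal protein genes were split at 12 weeks, 38 of 143 up and 36 down (median 0.07, mean −0.00, adjusted p = 0.954). Cell cycle genes rose in 34 of 76 and fell in 14 (adjusted p = 0.118), with cyclin-D3-1 (Cs3g23120), a driver of division, up by 3.17 (SE 0.12). Auxin genes rose in 50 of 120 and fell in 33, and cytokinin genes in 17 and 11 of 40, with neither list called. The cytokinin list took any description with the words response regulator. Its member APRR2 (Cs7g22610) therefore need not be a cytokinin gene. Adjusted over the list alone, cell cycle genes numbered 34 and 15, auxin genes 50 and 34, and cytokinin genes 17 and 11.

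**Figure D2:**
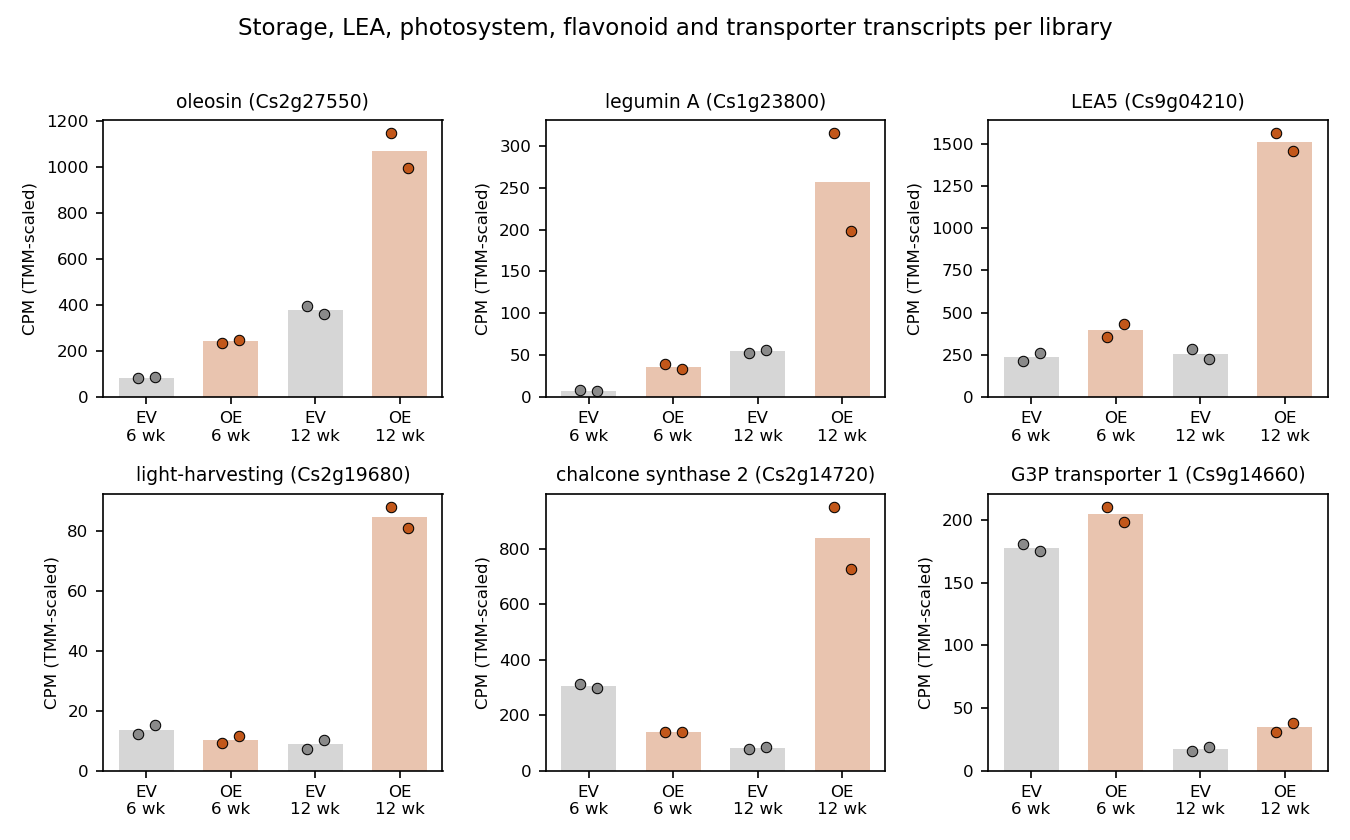
Transcript levels (y axis, CPM) of an oleosin, legumin A, Lea5, a light-harvesting protein, chalcone synthase 2 and glycerol-3-phosphate transporter 1; bars give group means and points the 2 libraries of each group. Oleosin Cs2g27550 was higher in the overexpression line at both times, and the light-harvesting gene Cs2g19680 was at 8.76 CPM in the empty vector and 84.4 CPM in the overexpression line at 12 weeks.

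The calls at the 2 times were then compared, to ask whether the same genes were affected. FUS3, oleosin Cs2g27550, LEA gene Cs1g13160 and legumin A were called up at both times, and none of their effects was called different between the times (adjusted p of at least 0.31). Among the 5 oleosins the effect was higher at 12 weeks for 1 and lower for 2. Adjusted over the list alone these were 1 and 3. The median difference was −0.75, and camera did not call the list (adjusted p = 0.46). Shared rises numbered 924, where 492.7 were expected for independent calls (odds ratio 3.23, two-sided Fisher exact test p = 2.7e-115). Shared falls numbered 759 (expected 399.4, odds ratio 3.22, exact p = 2.3e-96), and 548 genes were called in opposite directions, for which no expected number was computed. The Fisher test takes genes as independent units, which they are not. Both comparisons set the same 2 lines against each other, so shared calls do not separate CsFUS3 from other differences between the lines. The overexpression effect itself differed between the times for 6136 genes, 2946 with a higher and 3190 with a lower log2 effect at 12 weeks. Which side was larger depended on the setting, with 3067 and 3049 under RLE scaling, 2298 and 1829 without the genes of shifted segments, and 1641 and 1019 at a 2-fold minimum. SERK1 fell at 6 weeks and rose at 12 (difference of log2 effects 4.86, SE 0.22, adjusted p = 1.1e-13), as did chalcone synthase 2 (4.49, SE 0.16). Nitrate transporter NRT1.5 (orange1.1t00223) rose by 1.41 (SE 0.15) at 6 weeks and fell by 2.78 (SE 0.19) at 12, and the effect on PYL9 was smaller at 12 weeks (difference −0.72, SE 0.16).

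**Figure D3:**
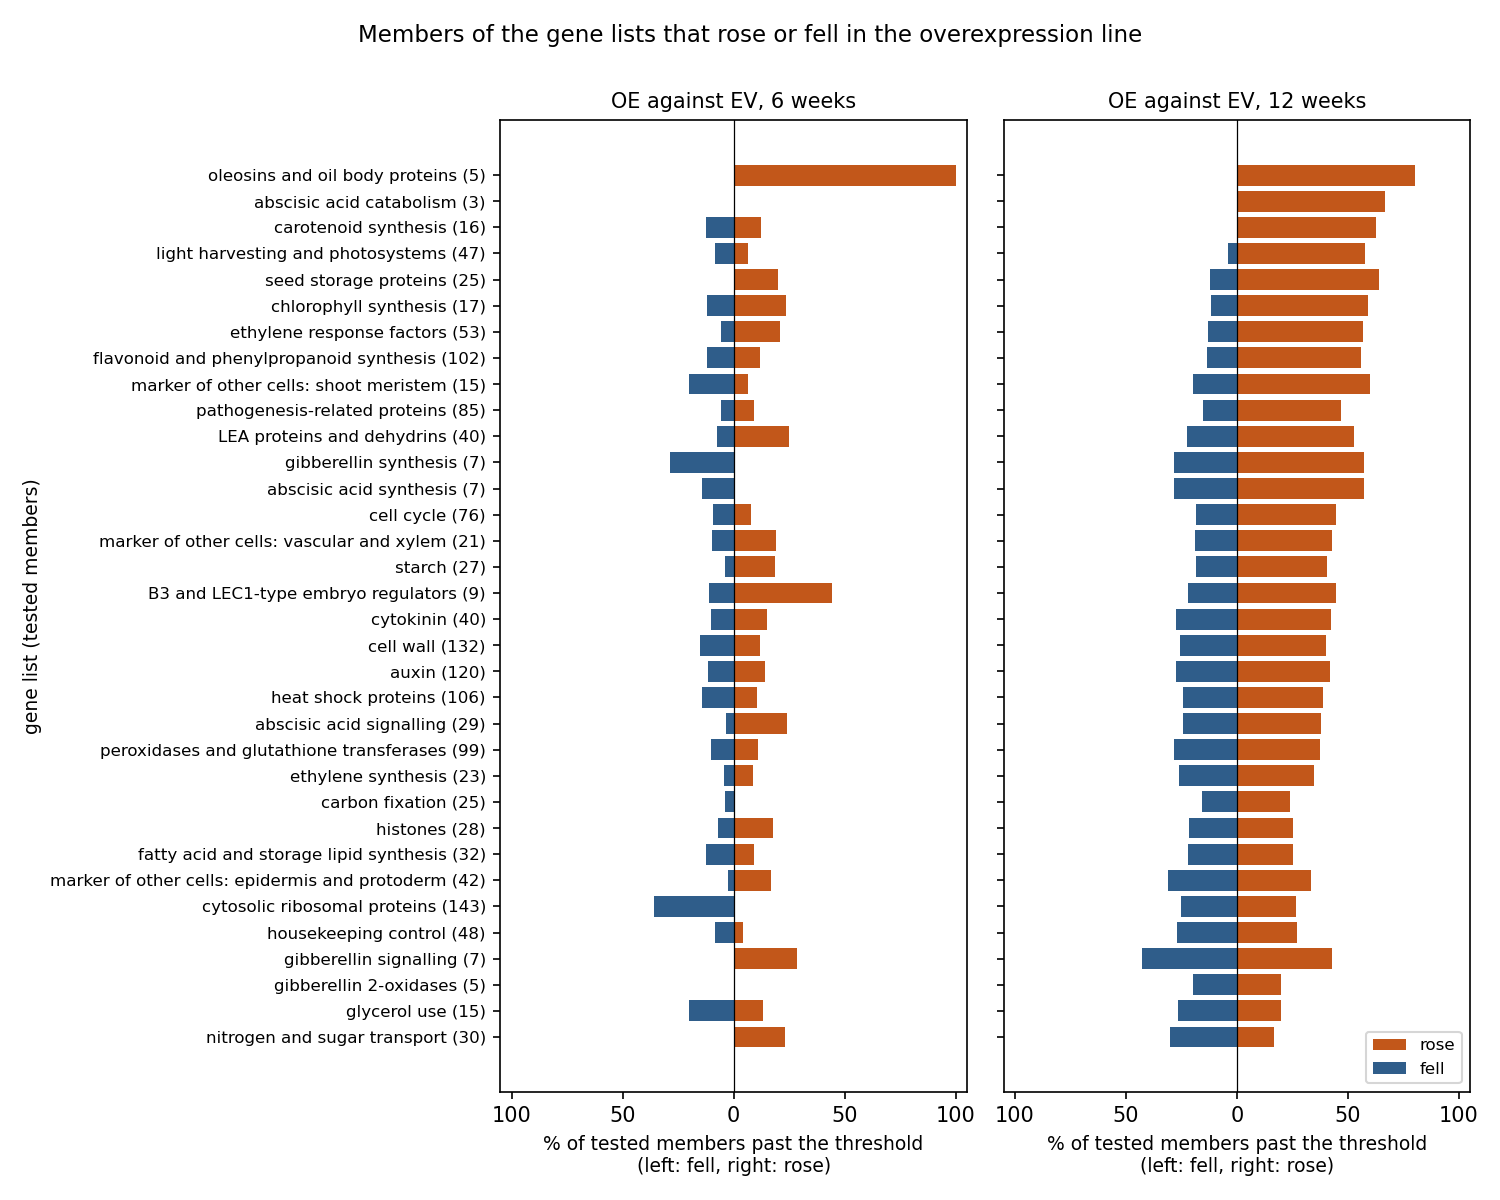
Share of the tested members of each gene list (x axis, percent) that rose (right) or fell (left) in overexpression against empty vector callus at 6 and 12 weeks, with tested members in brackets. Oleosins rose in 5 of 5 at 6 weeks, and light harvesting genes rose in 27 of 47 at 12 weeks.

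Between 6 and 12 weeks in the empty vector line, the control course of induction, oleosins, legumin A and vicilin rose while a glycerol-3-phosphate transporter fell. Oleosin Cs2g27550 rose by a log2 fold change of 2.20 (SE 0.10), legumin A by 2.85 (SE 0.26, adjusted p = 4.7e-05; the median of its chromosome was 0.12) and the vicilin gene Cs8g17030 by 3.29 (SE 0.37, adjusted p = 2.2e-03). The seed storage list as a whole was not called, with 8 of 25 members up and 5 down, also over the list alone (median 0.08, mean 0.05, test down at adjusted p = 0.901). Glycerol-3-phosphate transporter 1 (Cs9g14660) fell by 3.36 (SE 0.12), from 178 to 17.4 CPM, and chalcone synthase 2 by 1.89 (SE 0.11). Protein phosphatase 2C 3 rose by 1.89 (SE 0.12), and copalyl diphosphate synthase (Cs5g31210), which begins gibberellin synthesis, fell by 1.56 (SE 0.12). A heat shock gene (Cs5g03150, Hsp83) fell by 2.57 (SE 0.10). FUS3 rose by 0.45 (SE 0.11, adjusted p = 3.1e-03), a call lost without replicate 1 at 6 weeks (adjusted p = 0.089).

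All 5 oleosins rose over time in the empty vector line, also over the list alone (median 1.51, adjusted p = 6.4e-04, or adjusted p = 0.405 with an estimated correlation). Ribosomal protein genes rose in 106 of 143 members with none falling (111 over the list alone; median 0.50, adjusted p = 4.6e-14, or adjusted p = 0.58 with an estimated correlation), S26-3 (orange1.1t01197) by a log2 fold change of 0.91 (SE 0.09). Peroxidases and glutathione transferases rose in 34 of 99 and fell in 12 (39 and 13 adjusted over the list alone; adjusted p = 0.0106, or adjusted p = 0.58 with an estimated correlation). Carotenoid genes fell in 5 of 16 with none rising (median −0.39, adjusted p = 0.0145, or adjusted p = 0.58 with an estimated correlation), prolycopene isomerase (orange1.1t01907) by 0.99 (SE 0.16). Cell cycle genes fell in 25 of 76 and rose in 11 (28 and 11 adjusted over the list alone; adjusted p = 0.043, or adjusted p = 0.405 with an estimated correlation), cyclin-A2-1 (Cs4g20290) by 0.97 (SE 0.10). LEA genes rose in 11 of 40 and fell in 4 (15 and 5 adjusted over the list alone; adjusted p = 0.0269, or adjusted p = 0.607 with an estimated correlation). Leaving out one library ended 4 of these list calls. The peroxidase and LEA calls were lost without replicate 1 at 12 weeks (adjusted p = 0.0755 and 0.107), the LEA call also without replicate 1 at 6 weeks (adjusted p = 0.0546), the cell cycle call without replicate 2 at 12 weeks (adjusted p = 0.126) or either replicate at 6 weeks (adjusted p = 0.0671 and 0.0534), and the carotenoid call without replicate 2 at 6 weeks (adjusted p = 0.0501). The cell cycle call was also lost with the replicate number as a block (adjusted p = 0.063) and with lists matched on any protein hit (adjusted p = 0.432). The LEA call was lost with the word matches removed (adjusted p = 0.0818) and with any protein hit (adjusted p = 0.986). Over all genes 6408 differed, 3259 up and 3149 down, or 900 and 727 at a 2-fold minimum and 2321 and 2401 without the genes of shifted segments.

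The same interval in the overexpression line, the course of induction with added CsFUS3, brought rises in light harvesting and flavonoid transcripts. SERK1 rose by a log2 fold change of 3.41 (SE 0.15), the light-harvesting gene Cs7g27290 by 5.57 (SE 0.27) and phenylalanine ammonia-lyase (Cs7g24940), the entry to phenylpropanoids, by 3.62 (SE 0.13). Oleosin Cs2g27550 rose by 2.15 (SE 0.10), legumin A, on a segment with a median of −0.28, by 2.82 (SE 0.21) and ABA 8'-hydroxylase 1 by 4.91 (SE 0.31). PYL9 fell by 1.05 (SE 0.11), glycerol-3-phosphate transporter 1 by 2.56 (SE 0.11), and LEC2 by 2.10 (SE 0.14) on a chromosome 2 segment with a median of −0.74. FUS3 rose by 0.27 (SE 0.10, adjusted p = 0.031), a call lost without replicate 1 at 6 weeks (adjusted p = 0.32) and without either replicate at 12 weeks (adjusted p = 0.055 and 0.085).

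Lists called over time in the overexpression line rose on balance. Ribosomal protein genes rose in 116 of 143 and fell in 2 (119 and 3 adjusted over the list alone; median 0.79, adjusted p = 4.1e-15, or adjusted p = 0.372 with an estimated correlation). Flavonoid genes rose in 57 of 102 and fell in 17 (58 and 17 over the list alone; adjusted p = 1.1e-04, or adjusted p = 0.146 with an estimated correlation). Light harvesting genes rose in 27 of 47 and fell in 4 (median 1.48, adjusted p = 9.8e-04, or adjusted p = 0.402 with an estimated correlation). The seed storage list (16 up and 6 down of 25), ethylene response factors (24 and 6 of 53) and peroxidases (46 and 19 of 99) each had an adjusted p of 0.00558, or adjusted p = 0.372 with an estimated correlation. LEA genes (20 and 6 of 40, adjusted p = 9.7e-03) and pathogenesis-related genes (41 and 17 of 85, adjusted p = 0.0144) followed, with adjusted p = 0.403 and 0.354 with an estimated correlation. Chlorophyll synthesis (12 and 4 of 17) and housekeeping genes (21 and 8 of 48) were both at adjusted p = 0.0454, or adjusted p = 0.372 with an estimated correlation, and both calls were lost without replicate 2 of this line at 12 weeks (adjusted p = 0.116 and 0.0749) and without any one of the 4 libraries at 6 weeks (adjusted p = 0.0552 to 0.0667 and 0.0563 to 0.103). Without the genes of shifted chromosome segments the LEA, pathogenesis-related, chlorophyll and housekeeping calls were lost (adjusted p = 0.148, 0.0694, 0.148 and 0.122). With word matches removed the chlorophyll and housekeeping calls were lost (adjusted p = 0.055 and 0.075). With lists matched on any protein hit the LEA, chlorophyll, peroxidase and housekeeping calls were lost (adjusted p = 0.21, 0.166, 0.0691 and 0.0742), and with no low count filter the housekeeping call (adjusted p = 0.102). Adjusted over the list alone, the rising and falling members were 17 and 6 for seed storage, 21 and 7 for LEA, 41 and 18 for pathogenesis-related and 21 and 9 for housekeeping genes, and unchanged for light harvesting, ethylene response, peroxidase and chlorophyll genes. Housekeeping genes were chosen as a control, and 1 that rose was a glyceraldehyde-3-phosphate dehydrogenase (Cs4g01490, from 5.44 to 43.6 CPM). Over all genes 9689 differed, 4888 up and 4801 down. At a 2-fold minimum 2400 rose and 1312 fell, and without the genes of shifted segments 3811 and 3110.

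Groups from the deposited gene annotation were tested to look beyond the fixed lists. At 6 weeks 4 of 517 groups were lower in the overexpression line, among them the large ribosomal subunit, with 16 of 35 genes down and none up, and none was higher. At 12 weeks camera called 0 groups, with 63 at an unadjusted p under 0.05 and 14 with an estimated correlation. For the difference of effects it also called 0, with 64 and 17. Over time in the empty vector line 6 groups rose and 6 fell. DNA repair genes fell in 20 of 51 with 1 rising, and proteasome regulatory particle genes rose in 11 of 14. In the overexpression line 8 groups rose and 2 fell, and antioxidant activity genes rose in 29 of 51 and fell in 7. None of these calls was kept with an estimated correlation (adjusted p = 0.972, 0.978 and 0.89 for the 3 comparisons).

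Transcript levels also shifted along whole stretches of chromosomes. At 12 weeks the first part of chromosome 2, from 20535 to 4205005, had 370 genes with a median log2 difference of −0.79 between the overexpression and empty vector lines, and 87.0% of them were lower. LEC2 (3182652 to 3185740) and the gibberellin 2-oxidase gene Cs2g03380 lay inside it. On chromosome 1, 770 genes from 17290928 to 28779132 had a median of −0.47, and the first 70 genes a median of 0.49. At 6 weeks the shifts were smaller, 0.12 over the 1777 genes of chromosome 5 and 0.29 over the first 149 genes of chromosome 1. Over time in the empty vector line the 1342 genes of chromosome 1 had a median of 0.12. In the overexpression line it was −0.28 over 790 genes of chromosome 1, −0.74 over the same part of chromosome 2 and −0.17 over chromosome 5. With the genes of the segments shifted in any of these 4 comparisons left out, 2216 of 12965 genes differed at 6 weeks and 6777 at 12 weeks.

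**Figure D4:**
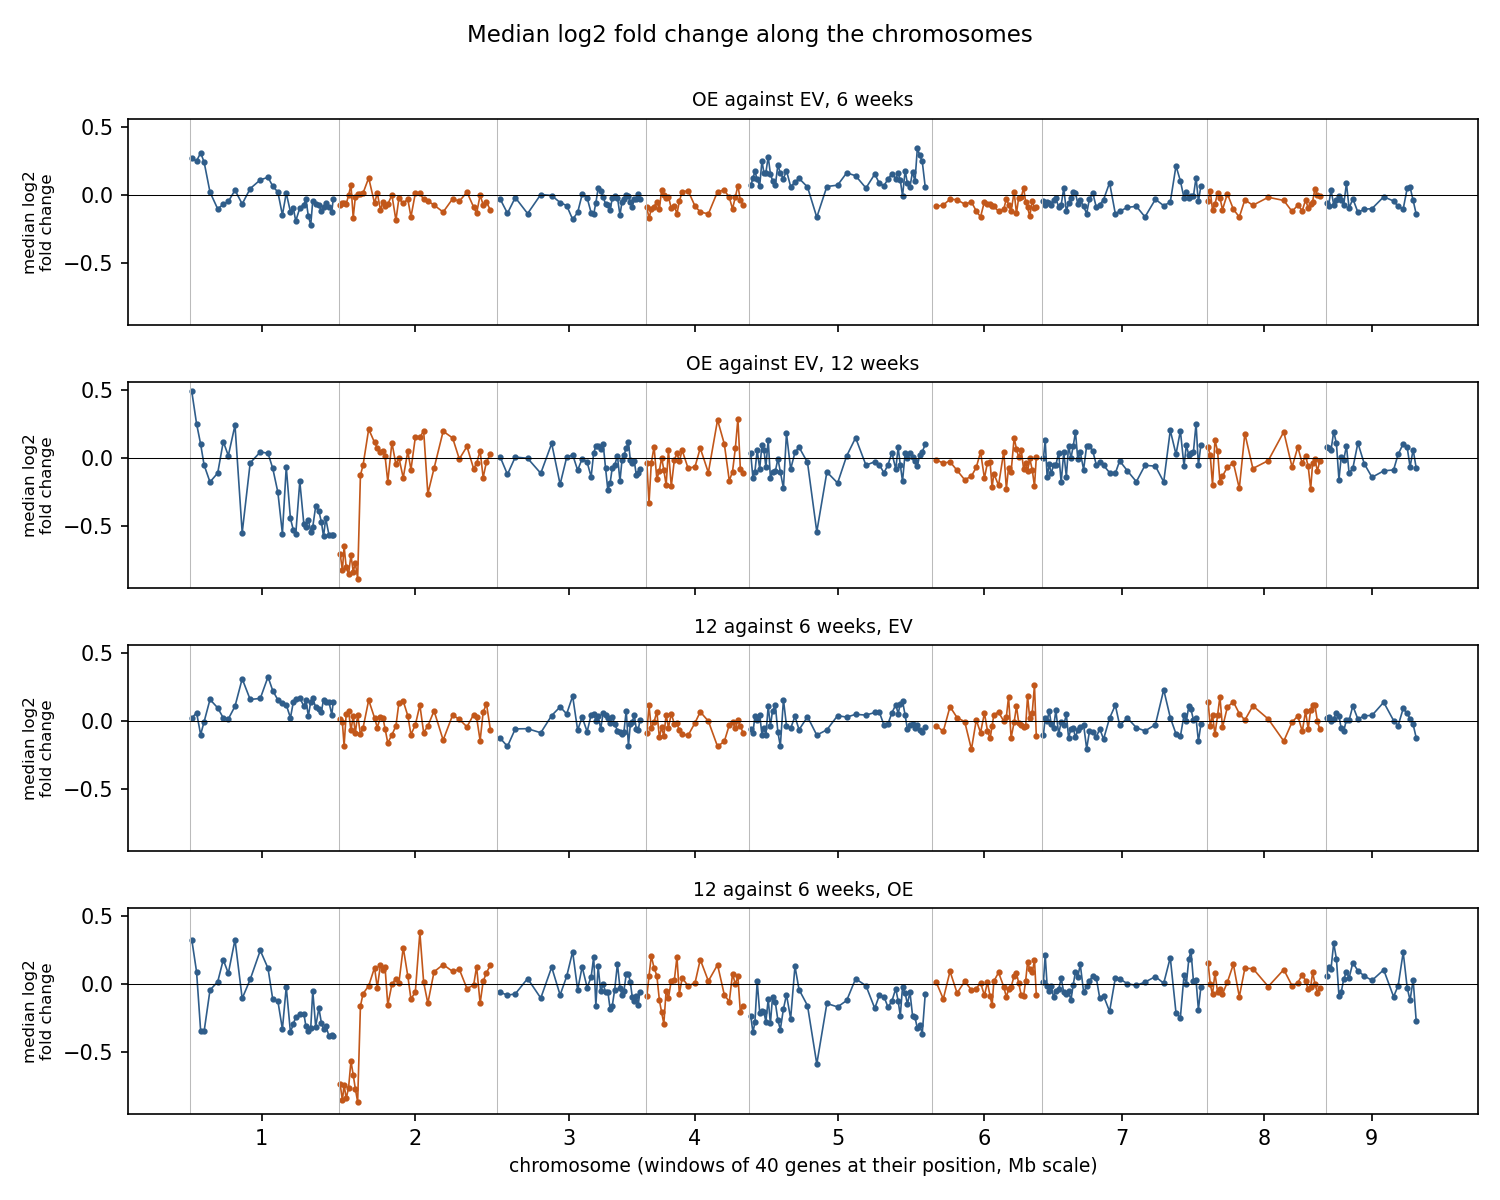
Median log2 fold change in windows of 40 neighbouring genes (y axis) along chromosomes 1 to 9 (x axis, position) for overexpression against empty vector at 6 and 12 weeks and for 12 against 6 weeks in each line. The start of chromosome 2 had a median of −0.79 at 12 weeks and −0.74 over time in the overexpression line.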

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

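Of the tests weighed here, those of chance gene order, green tissue and embryo tissue were chosen after the result was seen. The overexpression effect differed between 12 and 6 weeks, by a test of the difference itself, for 6136 genes. It differed for 11 gene lists, with these median differences of log2 effects: light harvesting 1.2505, seed storage 1.11, shoot meristem markers 1.65, carotenoid synthesis 0.67, flavonoid synthesis 0.66, pathogenesis-related genes 0.47 (0.57 with genes near 0 at their bounds), chlorophyll synthesis 0.43, ethylene response factors 0.35, ribosomal proteins 0.30, cytokinin 0.25 and the cell cycle 0.20. None of the list differences was called with an estimated correlation (lowest adjusted p 0.106, flavonoid synthesis). With word matches removed, 3 seed storage genes were tested, none of them was called for the difference, and their median was −0.03. The LEA list was not called for the difference (median −0.01, adjusted p = 0.194), but the 23 LEA genes left without word matches were, with 9 up and 4 down (10 and 5 adjusted over the list alone; median 1.66, adjusted p = 0.008, or adjusted p = 0.472 with an estimated correlation). The cytokinin and cell cycle differences were each lost in 7 of the 8 fits with one library left out (adjusted p = 0.0643 to 0.0937 and 0.0503 to 0.102). The exceptions were replicate 2 of the overexpression line at 6 weeks for cytokinin and replicate 1 of that line at 12 weeks for the cell cycle. The shoot meristem and pathogenesis-related differences were lost without replicate 2 of the overexpression line at 12 weeks (adjusted p = 0.0714 and 0.0522), and the ribosomal one without replicate 2 of the empty vector at 12 weeks (adjusted p = 0.0582). Fry, which tests a list against no change and not against other genes, gave adjusted p = 0.0728 for the ribosomal difference. Without the genes of shifted segments the ethylene response, cytokinin, pathogenesis-related and shoot meristem differences were lost (adjusted p = 0.0774, 0.199, 0.062 and 0.21). A filter at 5 CPM ended the cytokinin, pathogenesis-related and shoot meristem ones (adjusted p = 0.137, 0.0584 and 0.888), no low count filter the cell cycle and shoot meristem ones (adjusted p = 0.0662 and 0.0702), and the replicate block the cell cycle one (adjusted p = 0.0518). With lists matched on any protein hit the cytokinin, chlorophyll, cell cycle and shoot meristem differences were lost (adjusted p = 0.254, 0.0725, 0.984 and 0.186). The cytokinin list, which took any response regulator description, had no version with word matches removed. Its difference therefore need not be one of cytokinin genes.

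By the naming rule, 5 genes had a higher effect at 12 weeks with these adjusted p. They were for BCS1-B (Cs4g03390) at 6.6e-07, UGT76E11 (Cs8g19280) at 3.9e-04, bHLH68 (Cs4g16200) at 5.9e-07, the Rossmann-fold gene Cs3g13090 at 2.8e-11 and pectinesterase Cs2g07660 at 6.5e-04. The call of Cs2g07660 was lost without replicate 1 of the empty vector at 6 weeks. A lower effect at 12 weeks was found for calcium ATPase Cs3g10680 at 7.5e-11, the PP2-B10 gene Cs9g10790 at 7.6e-03, the polymerase fragments Cs5g14110 at 2.5e-07 and orange1.1t04733 at 1.4e-05, and glucan endo-1,3-beta-glucosidase Cs2g03340 at 8.2e-08, which lies in the shifted segment of chromosome 2.

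The first pattern weighed was the lower transcript level along the start of chromosome 2 in the overexpression line at 12 weeks. Chance order of the genes was not the source, since the split statistic was 16.5 and the highest of 1000 shuffled orders reached 4.59. A single library was not the source, with segment medians less other genes of −0.67 and −0.79 in the 2 libraries and within 0.03 of 0 in each 6-week library. Nor was noise of weak genes, since the more highly expressed genes had a median of −0.85 and the others −0.72. A shift of the whole distribution (−0.71, −0.75 and −0.68 at the 25th, 50th and 75th percentiles) is consistent with fewer copies of the segment in part of the cells, or with silencing of the segment, which transcript counts do not separate.

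The second pattern was the higher light harvesting and seed storage lists in the overexpression line at 12 weeks. Neither list was called by camera with an estimated correlation (adjusted p = 0.406 and 0.302). Of the 25 seed storage genes only 3 were left once word matches, mostly 7S globulin and lipid transfer or protease inhibitor genes, were removed, and 2 of them rose, too few to test as a list. List members inside shifted segments were not the source, since 99.8% and 84.2% of the list medians were kept outside the segments. This leaves open an effect of the segments on genes elsewhere, which was not tested. Gene length and level were not the source, since both medians stood at percentile 100 among 10000 matched random lists. The cleaned carbon fixation list had a median of −0.21 over 10 genes (SD 1.27, 1 up and 1 down, 8 not called). The cleaned light harvesting list had a median of 1.26 (SD 1.64). The medians lay further apart than the SD of the first list but not than that of the second. The test therefore does not decide on a larger share of green tissue. RuBisCO small chain Cs4g03580 rose by 2.82. The cleaned LEA list had a median of 2.55, and a larger share of embryo tissue cannot be told apart from higher levels per cell, because tissue share was not measured apart from the line.

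The third pattern was the lower ribosomal protein transcripts in the overexpression line at 6 weeks. The list was not called by camera with an estimated correlation (adjusted p = 0.763) or by fry (adjusted p = 0.0733). Gene length and level were not the source, since the list median of −0.25 stood at percentile 0 among 10000 matched random lists, whose median was −0.05. One library was not the source either, since the medians of the 4 library pairs were −0.21, −0.24, −0.25 and −0.27. No biological explanation was tested.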

How the results depend on the processing

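No call of a named gene or gene list turned into a call in the opposite direction under any alternative. The larger side of some gene counts did turn. Between the lines at 12 weeks 4753 genes were higher and 4723 lower, but 4663 and 4810 with library size alone. Of all calls, DESeq2 kept 75.9%, 86.7%, 82.1%, 86.6% and 81.8% in the same direction, in the order of the 5 comparisons. Limma on RPKM with no filter kept 52.4%, 88.1%, 76.0%, 88.5% and 78.0%. Named genes were mostly chosen for a small adjusted p or a large change in these data, which favours keeping their calls. Of 676 results of named genes, 641 kept their call with DESeq2, 674 with RLE scaling or library size alone, 672 with no low count filter, 653 to 654 with limma on RPKM and 628 with no filter there. Weaker were 34 with DESeq2, 2 with either other scaling, 4 with no low count filter, 15 to 16 with limma and 48 with no filter there, and any others had no value under that setting. Leaving out one library weakened 13 to 46 of them; the group then left with 1 library was assumed to vary like the others. The count at 6 weeks moved most. It was 5242 with only the 4 libraries of that comparison, which pool the spread of fewer groups, 1844 with limma on RPKM with no filter, and 1473 to 4000 with one library left out (1611 and 1571 without replicates 1 and 2 of the empty vector at 6 weeks, 1473 and 1608 without those of the overexpression line). At 12 weeks the count went the other way, from 9476 to 8501 with only the 4 libraries of that comparison. The median absolute log2 ratio between replicates was 0.118 (empty vector) and 0.121 (overexpression) at 6 weeks. At 12 weeks it was 0.172 and 0.162. All 4 groups shared one spread in the main fit, so the contrast of 3274 and 9476 calls depends in part on that choice. Whether the unequal spread moved the counts was not tested. A 2-fold minimum by construction kept fewer genes, 719 and 3605 between lines at 6 and 12 weeks, 1627 and 3712 over time in the empty vector and overexpression lines, and 2660 for the difference of effects. With the replicate number as a block the 5 counts were 3018, 9256, 6117, 9454 and 5849. Correlations of replicate deviations between groups were −0.05 to 0.04, so no deviation shared by replicate number was seen. Whether libraries of equal number were handled together is not stated. With genes of shifted segments left out, chosen after seeing the data, the 5 counts were 2216, 6777, 4722, 6921 and 4127 of 12965. Gene lists were called 37 times, 34 up and 3 down; with an estimated correlation, in the fixed or the cleaned lists, they were called 0 times, and with fry, which does not compare a list with other genes, 114 times (96 up and 18 down). Calls kept numbered 37 under either other scaling, 33 with either other filter, 35 with the block, 26 with lists matched on any hit and 25 without shifted segments. Annotated groups were called 26 times, and 0 times with an estimated correlation. The odds ratios of shared calls were 2.99 to 4.16 with one library left out, and 3.30 in both directions at unadjusted p under 0.01. A second kind of read count, planned as an alternative, was not run because the files held one kind. At the depth of these libraries, genes near 0 in one group give folds only as bounds.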

Other observations

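Several genes of the phosphate starvation response fell between 6 and 12 weeks in both lines. This list, with 2 others below, was chosen after such changes had been seen, so its counts describe the data and no test of it is given. Of 52 tested genes 34 fell and 3 rose in the empty vector line (median log2 change −1.42), and 36 fell and 6 rose in the overexpression line (median −1.25). A monogalactosyldiacylglycerol synthase-like gene (Cs4g05250), for a galactolipid of plastid membranes, fell by 7.46 (SE 0.19) in the empty vector line, from 101 to 0.558 CPM, and by 3.76 in the overexpression line. A gene of the SPX type (orange1.1t00194), a family of phosphate sensors, fell by 6.13 (SE 0.20), and phospholipase D p1 (Cs3g14760), which acts on membrane phospholipids, by 5.25. In the overexpression line purple acid phosphatase 8 (Cs2g17970) fell by 5.22. Between the lines 5 rose and 6 fell at 6 weeks, and 21 rose and 10 fell at 12 weeks.

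F-box genes of the PP2 type rose over time in the empty vector line, 8 of 15 with 1 falling (median 1.12), against 5 and 3 in the overexpression line. Of 127 transposon-like gene models 6 rose and 3 fell between the lines at 6 weeks, and 38 rose and 24 fell at 12 weeks. Phosphoenolpyruvate carboxykinase (Cs3g16700), an enzyme of sugar formation from organic acids, fell by 4.83 (SE 0.23) over time in the overexpression line and was lower than in the empty vector line at 12 weeks by 4.14. The clock-related genes PRR37 (Cs8g17520) and APRR7 (Cs6g03960) fell by 1.64 and 1.65 over time in the empty vector line, and the sampling hour is not given in the labels. The response regulator-like gene APRR2 (Cs7g22610), of the cytokinin list, rose by 5.13 (SE 0.20) in the overexpression line at 12 weeks, from 2.24 to 78.7 CPM. Sugar transporter SWEET16 (Cs3g14550) had 1 read in the empty vector line at 12 weeks against 23.2 CPM, and a beta-amylase (Cs2g22040), which degrades starch, had a count ratio of 417 (exact 95% interval 115 to 3452, which covers counting error only).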
